A study of Homo sapiens with 6 samples.

How the data were processed

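Small RNA was measured in 6 libraries of BEAS-2B, an established immortalised human bronchial epithelial cell line. Per the labels, 3 libraries came from cells given the empty plasmid pcDNA3.1 (control) and 3 from cells given a PRMT1 expression plasmid, each for 48 h. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Per the series' design text, reads were sequenced and filtered by BGI on its BGI-500 platform. The tools HISAT, Bowtie2 and RSEM and the genome build GRCh37.p13 are named per the submitters' processing notes, without versions. Which of them made the tables, how reads with several matches were divided and whether strand was used were not given in the sources used here. The library protocol in the labels describes messenger RNA enrichment or ribosomal RNA removal, whereas the tables hold small RNA classes.

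Each table lists, per the file headers, a small RNA identifier, a count, a class, a description and a TPM value. The deposited counts were whole reads per feature, not normalised. The TPM values deposited by the authors equalled the CPM of the library total, with no length term, to within 0.005 in every library, and were used only for that check. Features with no reads in a library are absent from its table and were taken as 0. The total count per library ran from 23.95 M to 25.79 M. A count of 3, taken as the limit that a count of 0 allows, corresponded to 0.183 to 0.26 CPM of known miRNA counts before TMM scaling, and this limit covers counting error only.

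The comparison used rows of the class of known mature miRNAs, 1727 names over the 6 libraries. Features with low counts were removed with filterByExpr of edgeR, which left 668 names holding 99.98% of the known miRNA counts. Libraries were scaled with TMM factors, and groups were compared with the robust quasi-likelihood test of edgeR without a block. Calls were made at a Benjamini-Hochberg adjusted p of 0.05. Unless another tool is named, adjusted p-values are from this test. CPM values are relative to the known miRNA total after TMM scaling, given as mean ± SD with n = 3 per group. SEs of log2 fold changes were taken as the fold change divided by the root of the F statistic.

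Before the data were examined, 21 lists of miRNAs were written down, covering epithelial identity, epithelial-mesenchymal transition (EMT) and fibrosis, let-7, miR-17-92, p53, NF-kB and inflammation, miR-15/16, miR-29 and miR-30, hypoxia, the 14q32 and chromosome 19 clusters, mirtrons, other miRNAs independent of DROSHA or DICER, and markers of muscle, blood, endothelial, liver, fibroblast, neural, pluripotent and kidney cells. Names that the tables join with a comma were matched by each part. Lists with at least 3 tested members, 17 in all, were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. Composition measures were compared with two-sided exact permutation tests, for which 3 against 3 libraries cannot give a p below 0.1.

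The named miRNAs followed a rule fixed before the data were examined. It took up to 12 miRNAs of smallest p per direction among those past the threshold. Where fewer than 6 passed, it took the 6 of smallest p in that direction, given as values. It added the 10 miRNAs of highest mean CPM, the up to 4 tested members of highest mean CPM from each list, whether or not they passed. It also took any list member past the threshold when adjusted over the list alone and, among miRNAs past the threshold with a mean CPM of at least 100, the 5 of largest fold change. Other names are stated to have been chosen after their values were seen.

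Hairpin positions came from GENCODE release 29 on GRCh38, which is not the build of the submitters' processing notes, and 1643 of the 1727 names matched a hairpin there. Names were called linked where their hairpins shared 18 bases with at most 1 mismatch on either strand, which held for 215 of the 668 tested names. These are uncertain, since counting could divide their reads. No let-7 name was among the names matched to a hairpin, so links of let-7 names were not assessed. The absence of a link therefore does not clear let-7 names of shared reads.

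The alternatives chosen before the data were examined were other scalings (RLE, upper quartile, library size only), DESeq2, limma-voom, no filter and a stricter filter of CPM 10 in 3 libraries. They also included the replicate number as a block, all classes of rows, omission of the most abundant miRNA, joining of hairpin rows, and omission of each library. Summing or omitting linked names, DESeq2 on the filtered names, and omission of each library for the composition measures and the other RNA classes were added after the data had been seen. The alternatives set aside for normalised values did not apply. The test was tried on 5 simulated data sets with 200 changed miRNAs each, among 659 tested names. It recovered 34.2% of the 2-fold, 92.7% of the 4-fold and 99.4% of the 8-fold changes, with 3.9% of calls false. Counts were drawn from a negative binomial model, in which no library stood apart. Data sets with fewer changed miRNAs were not simulated, so these shares may not hold for the real comparison. Computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The messenger RNA of PRMT1 is not a feature of these tables, so its over-expression was not measured here.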

Results

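Small RNA was profiled in BEAS-2B bronchial epithelial cells carrying an empty plasmid (control, n = 3) or a plasmid expressing PRMT1, a protein arginine methyltransferase (n = 3), after 48 h. The comparison asked how the miRNAs of these cells respond to PRMT1. Total counts were 24.49 M, 25.09 M and 24.01 M in control libraries 1 to 3 and 24.04 M, 25.79 M and 23.95 M in PRMT1 libraries 1 to 3. Known miRNAs took 12.39 M, 16.42 M and 11.54 M of these counts in control and 14.43 M, 11.91 M and 12.13 M in PRMT1 libraries. Replicates were not copies of one library, since the smallest chi-square per degree of freedom between any pair of libraries was 454.2 over 451 miRNAs.

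The miRNA content was dominated by miR-21-5p, a miRNA abundant in many epithelial lines, in both groups. It took 56.2% ± 8.73 (SD, n = 3) of known miRNA counts in control and 58.0% ± 1.06 (SD, n = 3) in PRMT1 libraries, with an exact permutation p of 0.8. The 10 most abundant miRNAs held 74.7% ± 4.81 and 75.3% ± 0.511 of known miRNA counts, with an exact permutation p of 1.0. Known miRNA totals (13454242 ± 2607780 and 12820832 ± 1394236, exact permutation p = 0.8) and numbers of known miRNAs detected (1303 ± 57.0 and 1336 ± 46.9, exact permutation p = 0.5) also overlapped between groups. The smallest p that this design allows is 0.1. Control library 2 stood apart from the other libraries, with miR-21-5p at 66.04% of its known miRNA counts and reads of the mir-21 precursor family at 2.89% of all counts, against 0.224% to 0.345% in the other libraries. Reads from exons of longer genes were 4.23% ± 1.42 of all counts in control and 6.07% ± 0.649 in PRMT1 libraries without overlap, with an exact permutation p of 0.1 and a Benjamini-Hochberg value of 1.0 over 14 RNA classes.

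The 10 most abundant miRNAs did not pass the threshold, and their groups overlapped. MiR-21-5p stood at 598400 ± 234300 CPM in control and 567100 ± 28730 CPM in PRMT1 libraries, a log2 fold change of -0.08 (SE 0.25). That fold change was 0.27 without control library 2 and -0.29 without control library 3. The 10 included members of the let-7 family, which restrain proliferation and growth genes, with let-7i-5p at 27060 ± 6431 and 26660 ± 1689 CPM, let-7a-5p at 25820 ± 5486 and 25930 ± 1825 CPM, and let-7f-5p at 16480 ± 3762 and 15820 ± 536.3 CPM. Whether let-7 names could share reads was not assessed. Log2 fold changes were -0.12 (SE 0.17) for miR-16-5p, 0.07 (SE 0.17) for miR-222-3p, -0.07 (SE 0.15) for miR-100-5p and -0.20 (SE 0.15) for miR-146a-5p, a miRNA induced by NF-kB. MiR-27a-3p had a log2 fold change of 0.29 (SE 0.49), and of -0.11 without PRMT1 library 3. MiR-24-3p was at 30980 ± 32530 CPM in control and 14690 ± 5314 CPM in PRMT1 libraries (log2 -1.08, SE 0.85). Its control libraries held 11760, 12660 and 68540 CPM, and without control library 3 its log2 fold change was 0.21.

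No known miRNA passed the threshold between PRMT1 over-expression and control, 0 of 668 with edgeR, and the lowest adjusted p was 0.352. At an unadjusted p under 0.05 there were 36 miRNAs, 19 higher and 17 lower in PRMT1 libraries, where 33.4 would be reached by chance. DESeq2 called 4 miRNAs and limma-voom 0. In 68 miRNAs (10.2%) the groups did not overlap, and chance gives 10%. The 6 miRNAs of smallest p with a higher mean in PRMT1 libraries, none past the threshold, were miR-378e, miR-1296-5p, the joined name miR-548ad-5p and miR-548ae-5p, miR-383-5p, let-7d-3p and miR-185-3p. MiR-1296-5p, from an intron of JMJD1C (chromosome 10, 63372957 to 63373048, GRCh38), was at 24.3 ± 4.32 CPM in control and 60.8 ± 19.7 CPM in PRMT1 libraries, a log2 fold change of 1.32 (SE 0.30, adjusted p = 0.352). Let-7d-3p was at 167 ± 65.8 and 316 ± 43.5 CPM (log2 0.92, SE 0.31, adjusted p = 0.741). The other members had log2 fold changes of 1.63 for miR-548ad-5p and miR-548ae-5p (2.504 without control library 3), 1.33 for miR-383-5p (0.86 without PRMT1 library 3) and 0.97 for miR-185-3p, at means under 10 CPM.

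The 6 miRNAs of smallest p with a lower mean in PRMT1 libraries, also not past the threshold, were miR-548n, miR-378a-3p, miR-3605-5p, miR-93-5p, miR-196a-5p and miR-134-5p. MiR-93-5p, from an intron of MCM7 (chromosome 7, 100093768 to 100093847, GRCh38), was at 4886 ± 493.5 CPM in control and 3452 ± 423.5 CPM in PRMT1 libraries, a log2 fold change of -0.50 (SE 0.17, adjusted p = 0.741). MiR-196a-5p, encoded in the HOX gene clusters, was at 1870 ± 573.8 and 1150 ± 135.8 CPM (log2 -0.70, SE 0.25, adjusted p = 0.741), and its log2 fold change was -0.44 without control library 1. MiR-548n (log2 -1.85, SE 0.39, adjusted p = 0.352), from an intron of DPY19L1, was at 9.18 ± 3.46 and 2.53 ± 0.649 CPM. Its group of linked names, joined directly or through one another, holds 65 other names. Among these is the joined name miR-548ad-5p and miR-548ae-5p, whose fold change had the opposite sign, so these are not separate observations. Summed over the group, the log2 fold change was 0.07 (SE 0.21). That sum stood at 124.9 to 157.7 CPM, of which miR-548n held a small part. MiR-134-5p had a log2 fold change of -0.90 (SE 0.32), and of -0.51 without control library 1. That of miR-3605-5p was -1.14 (SE 0.39). Over 668 miRNAs the median SE of a log2 fold change was 0.337, and 0.252 over the 159 miRNAs of at least 100 CPM. Simulated 2-fold changes were recovered in 34.2% of cases where 200 miRNAs were changed, a setting that the real data need not share. Of the 31 named miRNAs with a log2 fold change of at least 0.3 in either direction, a limit set after the values were seen, 21 changed sign or moved by over 1.5 times when a library was left out, 9 of them without control library 1. Without a filter on low counts, 9 miRNAs passed, and without PRMT1 library 1, miR-378e passed.

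**Figure D1:**
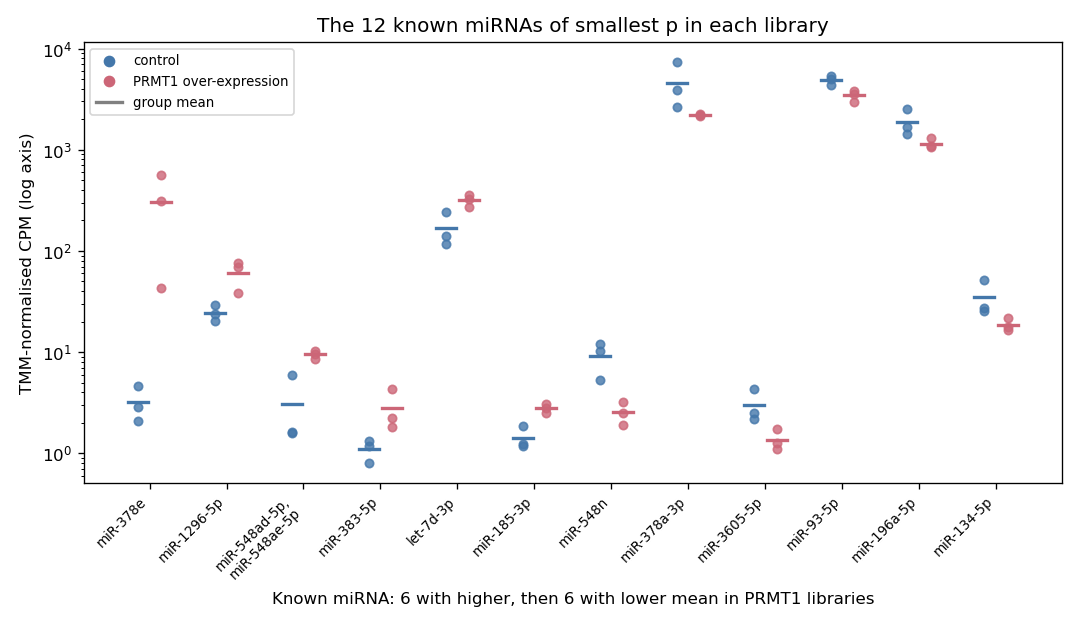
TMM-normalised CPM on a log axis for the 6 known miRNAs of smallest p with a higher and the 6 with a lower mean in PRMT1 libraries. Points are libraries (blue, control; red, PRMT1 over-expression; n = 3 each) and bars are group means; none of the 12 passed the threshold.

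The largest fold among these, that of miR-378e, lay in a family whose names share sequence. MiR-378e, from an intron of DOCK2 (chromosome 5, 170028488 to 170028566, GRCh38), was at 3.19 ± 1.30 CPM in control and 306 ± 262 CPM in PRMT1 libraries (log2 6.58, SE 1.12, adjusted p = 0.352). MiR-378a-3p, from an intron of PPARGC1B, a regulator of mitochondrial genes (chromosome 5, 149732825 to 149732890, GRCh38), was at 4602 ± 2410 and 2215 ± 59.6 CPM (log2 -1.06, SE 0.34, adjusted p = 0.741; log2 -0.57 without control library 1). MiR-378b and miR-378f were chosen after their values were seen. Counts of miR-378b were 20938, 5526 and 3 in control and 19, 1 and 0 in PRMT1 libraries, and those of miR-378f were 18, 2 and 8348 in control and 7367, 9 and 21 in PRMT1 libraries. Counts of miR-378e were 63, 26 and 37 in control and 656, 3760 and 6763 in PRMT1 libraries. All names but miR-378a-3p together held 12.4% to 20.6% of the miR-378 counts in every library. Summed over its names, miR-378 had a log2 fold change of -1.04 (95% interval -1.85 to -0.22, adjusted p = 0.743), and -0.53 without control library 1.

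**Figure D2:**
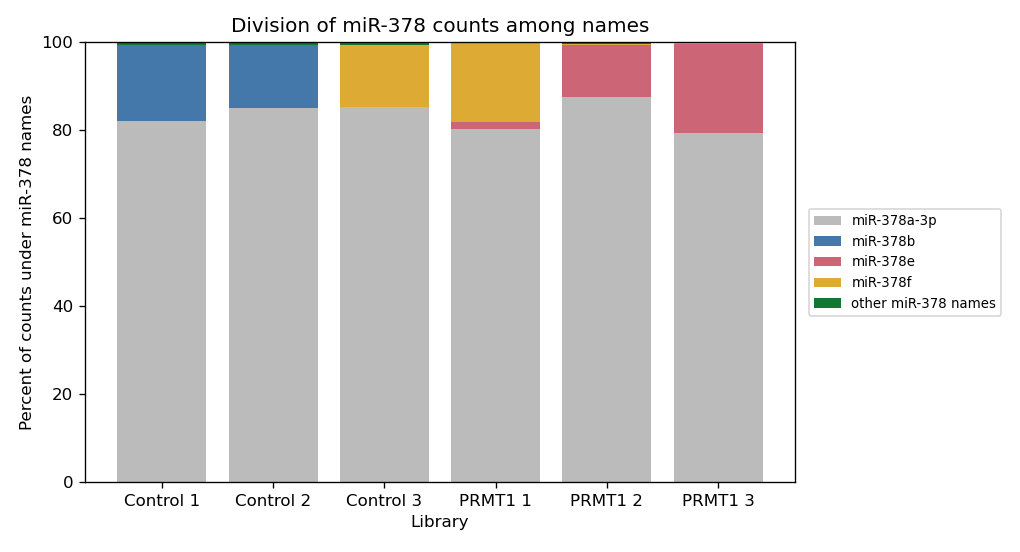
Percent of the miR-378 counts of each library that stood under each name, from 0 to 100%. MiR-378a-3p held 79.41% to 87.59%, and the remainder stood mainly under miR-378b in control libraries 1 and 2, miR-378f in control library 3 and PRMT1 library 1, and miR-378e in PRMT1 libraries 2 and 3.

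Of the lists fixed before the data were examined, 0 of 17 passed the threshold by camera, with an estimated correlation or by fry, and no member of any list passed when adjusted over the list alone. The epithelial list, centred on the miR-200 family and miR-205, which maintain epithelial identity, had a median log2 fold change of -0.01 over 8 tested members, 4 above and 4 below 0. Its most abundant members were miR-34a-5p (log2 -0.03, SE 0.17), which the p53 list also held, miR-200a-3p (log2 0.01, SE 0.19), miR-429 (log2 -0.28, SE 0.20; -0.16 without PRMT1 library 2) and miR-200b-3p (log2 -0.12, SE 0.22). MiR-205-5p, added after its values were seen, was at 4.82 ± 1.14 CPM in control and 7.93 ± 1.43 CPM in PRMT1 libraries without overlap (log2 0.72, SE 0.31, adjusted p = 0.741). The list of miRNAs that promote EMT and fibrosis had a median of -0.00 over 10 members, with miR-31-5p at -0.03 (SE 0.18) and miR-221-3p at -0.22 (SE 0.23), or 0.06 without control library 2. The NF-kB and inflammation list had 8 of 11 members below 0, with a median of -0.08, which was -0.20 without PRMT1 library 3, -0.18 without control library 3 and -0.12 without PRMT1 library 2. MiR-155-5p of this list was at -0.12 (SE 0.23), while miR-125b-5p was at 0.35 (SE 0.32), or -0.04 without PRMT1 library 2 and 0.61 without PRMT1 library 3.

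The miR-29 and miR-30 families, of which miR-29 restrains collagen genes, had a median of 0.31, and 8 of 8 members lay above 0 under each scaling tried. Over all 668 tested miRNAs, 325 to 402 lay above 0 under these scalings. All 8 members are linked names that could share reads, so they are not 8 separate observations. The median of this list was 0.15 without control library 1, 0.20 without PRMT1 library 1 and 0.52 without PRMT1 library 3. Without PRMT1 library 2, 6 of 8 members lay above 0, and 7 of 8 without control library 1 or PRMT1 library 1. MiR-29a-3p was at 7016 ± 2083 CPM in control and 9665 ± 2217 CPM in PRMT1 libraries (log2 0.46, SE 0.24; 0.24 without PRMT1 library 1 and 0.71 without control library 2). MiR-30b-5p was at 726 ± 82.1 and 881 ± 97.9 CPM (log2 0.28, SE 0.21; 0.17 without control library 2 or PRMT1 library 1). This list did not pass by camera (adjusted p = 0.587; adjusted p = 0.913 with an estimated correlation). The miR-17-92 group and its paralogous clusters, which promote proliferation, had 5 members above and 7 below 0 with a median of -0.02. Its members miR-93-5p and miR-25-3p (log2 -0.49, SE 0.19), both from MCM7, lay lower in PRMT1 libraries without overlap and did not pass the threshold. MiR-106b-5p of the same MCM7 cluster, added after its values were seen, was at 94.06 ± 19.99 and 122.6 ± 50.58 CPM (log2 0.38, SE 0.34), with a log2 fold change of -0.01 without PRMT1 library 1, 0.21 without control library 1 and 0.63 without PRMT1 library 3. Unlike miR-93-5p and miR-25-3p, it is a linked name, in a group with miR-17-5p and miR-20a-5p, and could share reads. The sum of that group had a log2 fold change of -0.06 (SE 0.20). MiR-92a-3p was at -0.16 (SE 0.22) and miR-20a-5p at -0.12 (SE 0.22). The median was -0.05 for the miR-15/16 family, with miR-15b-5p at -0.36 (SE 0.19) and miR-15a-5p at 0.25 (SE 0.21). These names are linked to each other and could share reads, and their sum had a log2 fold change of -0.24 (SE 0.17). For the let-7 family the median was -0.01, with let-7b-5p at 0.14 (SE 0.17). The p53 list had a median of 0.01 over 8 members, and the hypoxia list 0.25 over 6, where the mean was 0.04. The hypoxia median was 0.11 without control library 2, 0.07 without PRMT1 library 2 and 0.13 without PRMT1 library 3.

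Lists of miRNAs of unusual origin did not pass the threshold either. The imprinted 14q32 cluster had 22 members above and 20 below 0 with a median of 0.04, including miR-127-3p at 0.09 (SE 0.29) and miR-379-5p at -0.79 (SE 0.36), or -0.35 without control library 1. Mirtrons, which are spliced rather than cut by DROSHA, had a median of -0.05 over 7 members, and other miRNAs independent of DROSHA or DICER had a median of -0.06 over 3, with miR-320a-3p at -0.39 (SE 0.23) and miR-451a at 1.04 (SE 0.47). MiR-451a was at 0.43 without PRMT1 library 3, and miR-320a-3p at -0.23 without it and -0.68 without PRMT1 library 2. The chromosome 19 cluster had 1 tested member, miR-522-3p, at 1.42 ± 0.462 CPM in control.

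Markers of other cell types were also compared. The kidney list had the smallest camera p (adjusted p = 0.562; adjusted p = 0.913 with an estimated correlation) and a median of -0.60 over 5 members. It held miR-196a-5p, miR-196b-5p at 2707 ± 975.1 and 1787 ± 164.3 CPM (log2 -0.60, SE 0.26), miR-10a-5p (log2 0.04, SE 0.18) and miR-192-5p (log2 0.06, SE 0.21). Its other member, miR-194-5p, which the p53 list also held, had a log2 fold change of -0.615 (SE 0.33). That value was -0.41 without control library 1 and -0.38 without PRMT1 library 2. The median, which over all libraries was the value of miR-196b-5p, was -0.29 without control library 1 and -0.38 without PRMT1 library 2. Of the 5 members, 4 are linked names. MiR-196a-5p and miR-196b-5p are linked to each other and could share reads, and their sum had a log2 fold change of -0.65 (SE 0.25). Neural markers had a median of 0.14 over 7 members, with miR-138-5p at -0.05 (SE 0.20), and the median was 0.02 without PRMT1 library 3, 0.07 without PRMT1 library 1 and 0.09 without control library 1 or 2. The median was 0.79 for blood over 3 members, with miR-486-5p at -0.43 (SE 0.33; -0.07 without control library 1 and -0.72 without PRMT1 library 2) and miR-150-5p at 0.79 (SE 0.36). The blood median was the value of miR-150-5p, and was 0.40 without PRMT1 library 3. The median was 0.18 for fibroblasts and smooth muscle over 3, with miR-143-3p at 0.18 (SE 0.27), and -0.06 for muscle over 3, with miR-133a-3p at 0.19 (SE 0.30). The muscle median was -0.39 without control library 1, -0.34 without control library 3, -0.24 without PRMT1 library 3, -0.17 without PRMT1 library 2 and -0.09 without control library 2. The 2 endothelial members were miR-126-3p (log2 0.11, SE 0.20) and miR-126-5p (log2 0.05, SE 0.35). Of the liver marker miR-122-5p and the 8 pluripotency miRNAs, 0 had enough counts to be tested. In 10 of the 17 lists the median changed sign when a library was left out. Over these omissions it ran from -0.17 to 0.07 in the epithelial list, -0.11 to 0.16 in the EMT and fibrosis list, -0.18 to 0.17 in let-7, -0.17 to 0.16 in miR-17-92, -0.12 to 0.00 in the p53 list and -0.26 to 0.06 in miR-15/16. It ran from -0.07 to 0.03 in the 14q32 cluster, -0.37 to 0.04 in mirtrons, -0.27 to 0.17 in the other miRNAs independent of DROSHA or DICER, and -0.05 to 0.30 in fibroblasts and smooth muscle.

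**Figure D3:**
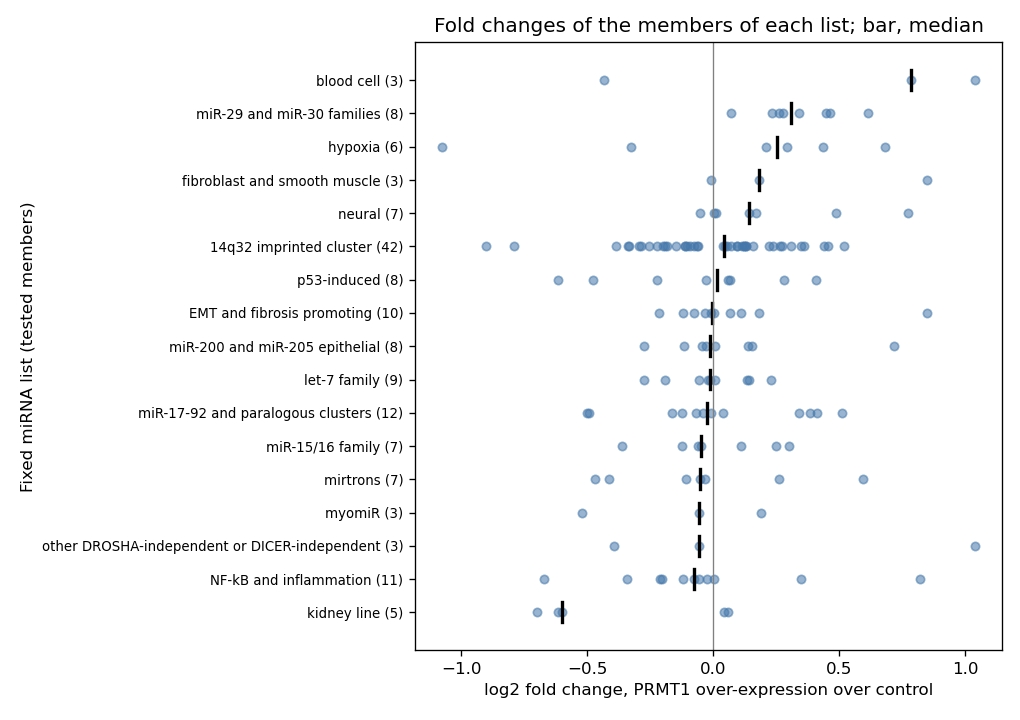
Log2 fold change of PRMT1 over-expression over control for each tested member (points) of the 17 lists with at least 3 tested members, with the median as a black bar. Medians ran from -0.60 in the kidney list (-0.29 without control library 1) to 0.79 in the blood list (0.40 without PRMT1 library 3), and 0 lists passed the threshold.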

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

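DESeq2 on the filtered names was added after the data had been seen, as were summing or omitting linked names and leaving libraries out of the composition measures. Summing or omitting linked names left let-7 names untouched, as none had been matched to a hairpin. The count of 0 known miRNAs with edgeR stayed 0 with RLE, upper quartile or library size scaling, limma-voom, a stricter filter, all rows, omission of miR-21-5p, either joining of hairpin rows, and summing or omitting linked names. Without a filter it was 9 (miR-1260b, miR-1296-5p, miR-1307-5p, miR-188-3p, miR-331-3p, miR-378a-3p, miR-4485-3p, miR-548ad-5p with miR-548ae-5p, and miR-548n). DESeq2 gave 4 (miR-12135, miR-378b, miR-378e and miR-548n), and 3 on the filtered names (the same without miR-12135). The cause was not tested, and names outside the rule were chosen after their values were seen. Leaving out each library gave 0 to 1, the 1 being miR-378e without PRMT1 library 1. With the replicate number as a block the count was 1, miR-378b. Correlations of the deviations of same-numbered libraries were -0.091, 0.195 and -0.122, within the -0.155 to 0.244 of libraries of different number. With 3 libraries per group, these values cannot exclude a pairing, on which the labels are silent. The count of lists stayed 0 in each alternative run. The 12 miRNAs of smallest p kept their sign in each alternative that tested their names. Signs differed from the reported one in 116 of 1430 values over the 74 named miRNAs. Directions by camera or fry differed in 21 of 197 values over the lists. None of these values passed the threshold. The difference in features detected, 33.3 for known miRNAs, was 127 over all rows, which count more features. Over all rows the difference in total was 64444 (-633410 for known miRNAs) and that in the share of the 10 most abundant miRNAs -1.81 percentage points of all counts (0.627 of known miRNA counts). The difference in features ran from 5.50 to 62.5 when a library was left out, the difference in known miRNA total from -1589104 to 851967, and that in the share of the 10 most abundant miRNAs from -1.10 to 3.37 percentage points. At these depths, a count of 0 allowed a level of 0.183 to 0.26 CPM of the known miRNA total before TMM scaling.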

Other observations

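The tests of the miR-378 names, of the division between opposite strands and of the arm ratio were chosen after the values had been seen, as were the omissions of libraries for the other RNA classes, the pairs on which the test of depth was run and the limit it was held to. When rows of all classes were fitted together with edgeR, 0 features passed the threshold. At an unadjusted p under 0.05 there were 64 of 1730, of which 28 were among the 671 known mature miRNAs. Over all classes, leaving out each library gave 0 to 1 past the threshold, and 25 to 183 at an unadjusted p under 0.05. The 1 came without PRMT1 library 1, where 0 predicted miRNAs, 0 piRNAs and 0 small nucleolar RNAs passed. The 178 small nucleolar RNAs, which guide modification of ribosomal RNA, had 57 members above 0 and a median log2 fold change of -0.18, with a camera p of 0.000916 and a p of 0.581 with an estimated correlation. This rested on PRMT1 library 1, where they held 0.208% of all counts, against 0.378% to 0.474% in the other libraries. Without that library the median was 0.11, with 112 of 184 members above 0 and a camera p of 0.209, and over the other omissions it ran from -0.46 without PRMT1 library 2 to -0.04 without PRMT1 library 3. Of the 74 tested predicted miRNAs and 677 piRNAs, 6 and 21 had an unadjusted p under 0.05, and 3 to 12 and 12 to 127 when a library was left out, the highest without PRMT1 library 2. Their camera p was 0.045 and 0.0134, and 0.535 and 0.304 with an estimated correlation, with 42 and 375 members above 0. When a library was left out, the camera p at the preset correlation ran from 0.011 to 0.86 for predicted miRNAs and from 1.06e-06 to 0.537 for piRNAs. These camera p-values were not adjusted over the classes.

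Mean CPM was higher for miR-378e and lower for miR-378b in PRMT1 libraries, neither past the threshold in the main edgeR test. DESeq2 called both, edgeR with the replicate number as a block called miR-378b, and edgeR without PRMT1 library 1 called miR-378e. MiR-378b had 3 counts in control library 3 against 19 in PRMT1 library 1. Summed over miR-378b, miR-378e and miR-378f, the level was 1543, 444 and 653 CPM in control and 523, 310 and 567 CPM in PRMT1 libraries. Over all 9 names but miR-378a-3p, the SD of the log2 sum between libraries was 0.77, against a median of 2.62 when the libraries of each name were re-ordered independently (one-sided permutation p = 0.020, 100000 re-orderings). That test restates the counts that prompted it, so division of reads among near-identical names stays open, as a possible explanation only. A changed amount of the whole family under PRMT1 over-expression also stays open. The sum with miR-378a-3p had a log2 fold change of -1.04, an interval of -1.85 to -0.22 and an adjusted p of 0.743. That log2 fold change was -0.53 without control library 1. A lower sum alone would not raise miR-378e, so it would not account for the division among names.

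Some miRNAs from opposite strands of one locus appeared to trade counts between libraries, and in examples chosen after their values were seen the share of miR-3184-3p in its sum with miR-423-5p ran from 3.5% to 95.9%, that of miR-374b-5p with miR-374c-3p from 1.8% to 97.8%, and that of miR-103a-3p with miR-103b from 5.0% to 93.1%. Over the 12 annotated pairs with both names tested, the median correlation of log2 CPM was -0.275, which lies within the middle 95% of random sets of pairs, -0.37 to 0.366 (one-sided permutation p = 0.077), a range that excludes nothing, so assignment of reads to either strand may apply to some pairs and cannot be told apart from chance over all. The answer depended on which pairs entered, since over 6 definitions tried after the data had been seen the median ran from -0.607 to 0.041 and the permutation p from 0.0061 to 0.60. The pairs as first defined, 16 of any arms, gave 0.013 (permutation p = 0.54), while a narrower set of 11 pairs of at least 1 CPM, the first to be tested, gave -0.469 (permutation p = 0.0076). A difference in depth stays open too: the median absolute correlation of the strand ratio with the known miRNA total was 0.229, below the median of 0.343 over 720 re-orderings, and 0.20 to 0.286 over the 6 definitions, but in 2 of them the upper end of its 95% interval over resampled pairs reached the level that depth would need.

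In 168 hairpins with both arms tested, the median log2 ratio of the less to the more abundant arm was -3.69 ± 0.099 (SD, n = 3) in control and -3.61 ± 0.024 (SD, n = 3) in PRMT1 libraries. The hypothesis that PRMT1 over-expression shifts this ratio stays open, as the difference of 0.081 came with overlapping groups and an exact permutation p of 0.2. Control library 2 lay lowest at -3.81, against -3.65 and -3.62 in control libraries 1 and 3 and -3.64 to -3.59 in PRMT1 libraries.

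The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 miRNAs and 0 lists past the threshold and the highest other split gave 1 and 1. At an unadjusted p under 0.05, the real split gave 36 miRNAs and the highest other split 72. On the first principal component, which held 36.1% of the variance, control libraries 1 and 2 lay at -13.2 and -12.7, and control library 3 (5.76) lay with the PRMT1 libraries (5.27 to 8.84).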
